A study of Mus musculus with 8 samples.

How the data were processed

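The counts per gene were made by the authors before the files were deposited: per the submitters' notes, reads were aligned to mm10/GRCm38 with TopHat2 2.0.10, handled with SAMtools and counted with HTSeq, and DESeq was named for the comparison. RNA was taken up with a MagMax-96 kit, checked on an RNA Pico chip and made into TruSeq Stranded mRNA libraries. The annotation release, the strand setting and the rule for ambiguous reads of the counting are not given in the sources used here. The reads themselves were not analysed here. The counts were used as they were, without any further adjustment by the authors that the sources name. Of the gene, no-feature and ambiguous counts together, 30.4 to 39.3% were no-feature counts and 0.471 to 0.554% were ambiguous, and both were left out. No-feature counts are those that the counting assigned to no gene. Gene names and positions came from GENCODE M21 (GRCm38), which held 40340 of the 41214 gene identifiers (97.9%). The other 874 carried at most 0.251% of a library's counts and were kept under their identifiers.

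Counts were normalized by trimmed mean of M values and filtered with filterByExpr, which kept 16456 of the 27639 genes with a count. All 8 libraries were fitted in edgeR 4.0.16 with 1 mean per group, by glmQLFit and glmQLFTest. The residual degrees of freedom were 4 and the biological coefficient of variation 0.45. Contrasts were deltaPOZ minus wt in B, in T, their mean, their difference (T minus B), and T minus B over both genotypes. P values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The SE of a fold change was its size divided by the square root of the F statistic. Other tools were limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3; tables and figures used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Levels are CPM with the trimmed mean of M values factors applied. Limits for genes at 0 rest on 3 counts over the unscaled library total and cover counting error only. Replicate numbers follow the order of the records and pair nothing.

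The 40 gene lists, the contrasts, the tests, the rule for named genes and the other settings listed first below were fixed before the data were examined. Lists were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 40 lists, and again with an estimated correlation and with fry. The lists cover B lineage identity, precursor B, mature B and plasma cells, MHC class II, T lineage identity, thymocyte stages, regulatory and effector T cells, Notch, Miz1 and its partners, reported Miz1 targets, p53 targets, cell cycle regulators, S phase, and G2 and M phase. They also cover the BCL2 family, ribosomal proteins, growth genes induced by Myc, deoxynucleotide metabolism, DNA damage, autophagy, lysosome, cytokine signalling, TGF-beta, interferon, NF-kB, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, immediate early genes and histones. Other cells were covered by lists for macrophages, neutrophils, dendritic, erythroid, platelet, NK and stroma cells, and sex by 5 sex-linked genes. Of the entries 815 matched a gene; Ighd, Vps28, Hist2h2bb, Hbb-b1, Hbb-b2 and Ahsp did not.

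Named genes are Zbtb17, then up to 10 per direction among called genes with a higher group mean of at least 5 CPM and replicates that do not overlap, without receptor segments or pseudogenes. Where no gene qualified, the 5 with the smallest p were given as values that did not pass. For B, where a single gene passed 0.05, genes at an adjusted p under 0.1 are also named. Of each list named, up to 4 members with the smallest p were eligible, and for T against B those with the largest fold. Which lists have their members named was chosen after the results were seen, as were Rpl22l1, Hes5 and the marker genes of single libraries. A few single-gene results are not reported here, though those genes stayed in every fit and list.

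The other settings tried were median-of-ratios size factors, DESeq2, limma-voom, a filter on a total of 10 counts, a filter of 5 CPM in 2 libraries, removal of receptor segments, each lineage alone, an additive model, a threshold of 0.1, and leaving out each library. After the data were seen, fits without chromosome 4 and without 3 doubted libraries (B wt 2, T wt 1, T deltaPOZ 2) were added. The chromosome work (CPM above 10, shift of 0.35, distal part from 120 Mb, neighbours within 10 Mb) was also set after looking at the data.

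The code was tested on simulated data with known changes. For B, edgeR recovered 2.99% of genes changed 2-fold, 44.8% of those changed 4-fold and 81.8% of those changed 8-fold, with 4 false calls. DESeq2 recovered 35.8, 74.6 and 97.0% with 71 false calls. For T edgeR recovered 2.99, 50.7 and 77.3%, for the average 19.4, 85.1 and 92.4%, for the difference 0, 11.9 and 54.5%, and for T against B 11.9, 58.2 and 81.8%, with 5, 6, 5 and 9 false calls. Camera found the moved list and 0 others of 40. The simulated genes varied independently of each other, so this check could not show how often correlated lists are called falsely. A shift of 0.4 given to a chromosome in 1 of 4 libraries was found as 0.286, with at most 0.0409 on another autosome. This check measured the library against the mean of all 4, itself included, which shrinks the shift. The shifts reported below were measured against the other libraries of the lineage only, so 0.286 does not gauge their recovery.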

Results

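Messenger RNA was sequenced from 8 spleen tumours of C57Bl6 mice. The labels name tumours of B cells and of CD4+ T cells, each with intact Miz1 (wt) or with a Miz1 that lacks its POZ domain (deltaPOZ). Miz1 is the product of Zbtb17, a zinc finger transcription factor that binds Myc, and the POZ domain lets its molecules join into multimers. Each of the 4 groups (B wt, B deltaPOZ, T wt, T deltaPOZ) held 2 libraries, and every library came from a separate mouse, so n = 2 biological replicates for every group mean and SD. The libraries held 56.7 and 44.3 M gene counts in B wt, 53.7 and 50.9 M in B deltaPOZ, 49.5 and 57.4 M in T wt, and 52.8 and 58.3 M in T deltaPOZ. At this depth a count of 0 allowed a level of up to 0.0515 to 0.0677 CPM, counting error only. Levels are given in CPM as mean ± SD, with counts scaled to the library total of the tested genes times its normalization factor (0.929 to 1.087). The limits for a count of 0 use the library total without that factor. Fold changes are given as log2 of deltaPOZ over wt with the standard error (SE). Calls rest on edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16456 genes unless another test is named. Where the replicates of 2 groups of 2 do not overlap, chance alone gives this for 33.3% of genes.

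The series title asks how the deletion affects expression in both kinds of leukemia. Principal components were computed on the genes that varied most, picked anew for each set of libraries. Their shares refer to the variance of those genes only. The first component of all 8 libraries, with 87.0% of that variance, separated B from T tumours. Among the B libraries alone the first component (51.9%) separated deltaPOZ from wt, while among the T libraries the first component (41.0%) did not and the second (32.1%) did.

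Zbtb17 itself (ENSMUSG00000006215, GRCm38 chromosome 4, 141444654 to 141467930) was measured at 66.1 and 48.0 CPM in B wt, 49.4 and 59.1 in B deltaPOZ, 49.6 and 42.3 in T wt, and 40.1 and 36.9 in T deltaPOZ. Its log2 fold change was -0.07 (SE 0.23) in B and -0.25 (SE 0.23) in T, and neither passed the test (edgeR adjusted p = 0.926 and 1). In B the sign turned without B wt 1 (0.18) and without B deltaPOZ 1 (0.10). A count over the whole gene lies mostly outside the deleted part, so these levels say little about the allele.

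Several features other than genotype differed between the libraries. Xist, the RNA that silences an X chromosome in females, stood at 975 and 1477 CPM in B wt and at 0.936 and 0.757 in B deltaPOZ, while the Y-linked Ddx3y stood at 174 and 133 in B deltaPOZ and at 0.0949 and 0.289 in B wt. Sex therefore followed genotype in the B tumours. All T libraries held both RNAs, with Xist at 1246 CPM and Ddx3y at 22.5 in T wt 1, and Xist at 11.8 to 35.4 and Ddx3y at 142 to 184 in the other 3. Lyz2 and S100a8, abundant in myeloid cells, reached 633 and 236 CPM in B wt 2. The haemoglobin gene Hbb-bs reached 153 CPM in B deltaPOZ 2 against 2.81 to 7.72 in the other B libraries, and ran from 2009 to 11082 in the T libraries. Rag1 and Dntt, which act in receptor gene rearrangement, stood at 8.30 and 5.13 CPM in T deltaPOZ 1 against 758 to 1069 and 112 to 417 in the other T libraries. T deltaPOZ 2 had counts in 25387 genes against 18339 to 21078 in the others.

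Whole chromosomes also stood apart in single libraries. In B wt 1 the expressed genes of chromosome 12 lay at a median log2 difference of 0.60 from the other B libraries, and in B deltaPOZ 1 those of chromosomes 3 and 4 lay at 0.53 and 0.45. In T deltaPOZ 1 those of chromosome 14 lay at 0.49. Beyond 120 Mb of chromosome 4, where Zbtb17, Rpl22, Eno1, Srm and Sdhb lie, both B deltaPOZ libraries were higher (0.36 and 0.34) and both B wt libraries lower (-0.34 and -0.36). The 270 tested genes there had a median log2 fold change of 0.56 in B, against -0.03 over the other autosomes, and 45.6% of them against 13.9% had an unadjusted p under 0.05.

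**Figure D1:**
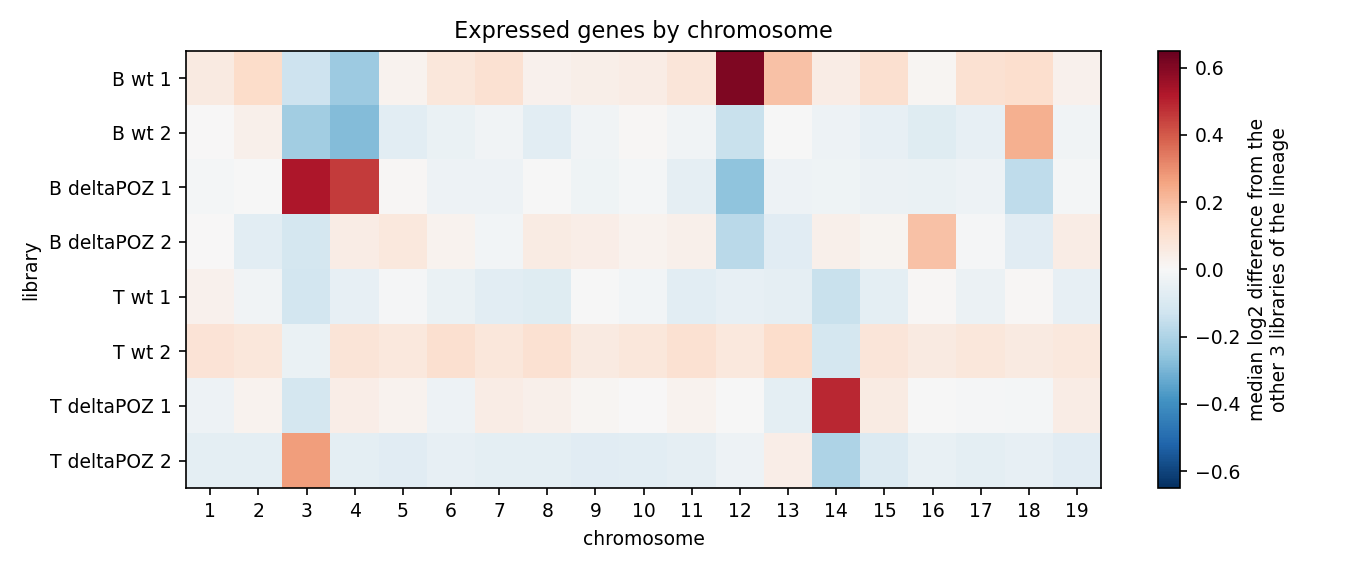
Median log2 difference of the expressed genes of each autosome (horizontal axis) from the other 3 libraries of the same lineage, for the 8 libraries (vertical axis). The strongest shifts are chromosome 12 in B wt 1 (0.60), chromosome 3 in B deltaPOZ 1 (0.53), chromosome 14 in T deltaPOZ 1 (0.49) and chromosome 4 in B deltaPOZ 1 (0.45).

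Several genes reported as direct targets of Miz1 were lower in deltaPOZ tumours of both lineages. Vamp4, a SNARE protein of vesicle fusion (ENSMUSG00000026696, chromosome 1, 162570515 to 162599084), went from 32.7 ± 6.0 to 9.41 ± 4.0 CPM in B and from 28.2 ± 0.97 to 13.5 ± 1.2 in T, a mean log2 fold change of -1.43 (SE 0.24). Exoc2, part of the exocyst that tethers vesicles, went from 124 ± 47 to 61.4 ± 2.0 in B and from 174 ± 5.7 to 99.2 ± 0.69 in T (mean -0.92, SE 0.18). The ribosomal protein gene Rpl22 (mean -0.66, SE 0.13) and the autophagy gene Ambra1 (-0.87, SE 0.21) were also lower in all 4 deltaPOZ libraries than in the wt libraries of their lineage. Tmem126a, a mitochondrial membrane protein gene, went the other way (0.64, SE 0.20). Rpl22l1, the paralog of Rpl22, stood at 182 ± 24 against 382 ± 180 CPM in B and 91.3 ± 13 against 210 ± 39 in T (mean 1.14, SE 0.24), with an adjusted p of 0.380 by edgeR.

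Of the 13 tested members of that list, 6 passed in the average over both lineages when adjusted over the list alone, 5 lower and 1 higher. Vamp4, Exoc2 and Rpl22 fell (edgeR adjusted p = 0.00686 each), as did Ambra1 (0.0123), and Tmem126a rose (0.0307). Over all genes 0 members passed by edgeR (smallest adjusted p = 0.278). Vamp4, Exoc2 and Rpl22 passed over the list alone in each of the 8 fits that left out 1 library. Ambra1 failed without T deltaPOZ 2, and Tmem126a failed in 5 of the 8 fits: without B wt 1, B deltaPOZ 2, T wt 1, T deltaPOZ 1 and T deltaPOZ 2. Within B alone 6 members passed over the list alone, 5 lower, among them Vamp4, Exoc2, Rpl22 and Ambra1, and Cdkn1c higher, a cell cycle inhibitor whose rise rested on B deltaPOZ 2 (12.8 CPM against 0.390 in B deltaPOZ 1). Fewer passed in B without any 1 library, from 2 to 4. Within T 0 passed by edgeR (smallest adjusted p = 0.0749). With each lineage fitted alone this turned: 0 passed in B (smallest edgeR adjusted p = 0.0549) and 3 in T, Ambra1, Exoc2 and Vamp4, all lower (smallest 0.0220). By fry, run on all libraries only, the list was lower as a set in the average (adjusted p = 0.0215) and in B (0.0283). In T it did not pass by fry (0.3675). By camera the set was lower in T (adjusted p = 0.01002) and in the average (0.00949), and did not pass in B (0.0586). With an estimated correlation the camera adjusted p was 0.648, 0.284 and 0.426 in that order. The set's call in T was lost without T wt 2 (0.0848), T deltaPOZ 1 (0.0680) or T deltaPOZ 2 (0.0602), and that of the average without B deltaPOZ 1 (0.0586). With the 3 libraries left out that were doubted after the data were seen (B wt 2, T wt 1, T deltaPOZ 2), both set calls ended (T 0.0858, average 0.136), as did those of Vamp4, Ambra1 and Tmem126a in the average. That fit kept 5 libraries in 4 groups, so its calls and lost calls rest on 1 residual degree of freedom. The deltaPOZ effect on the list did not pass a test of difference between the lineages (camera adjusted p = 0.745).

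**Figure D2:**
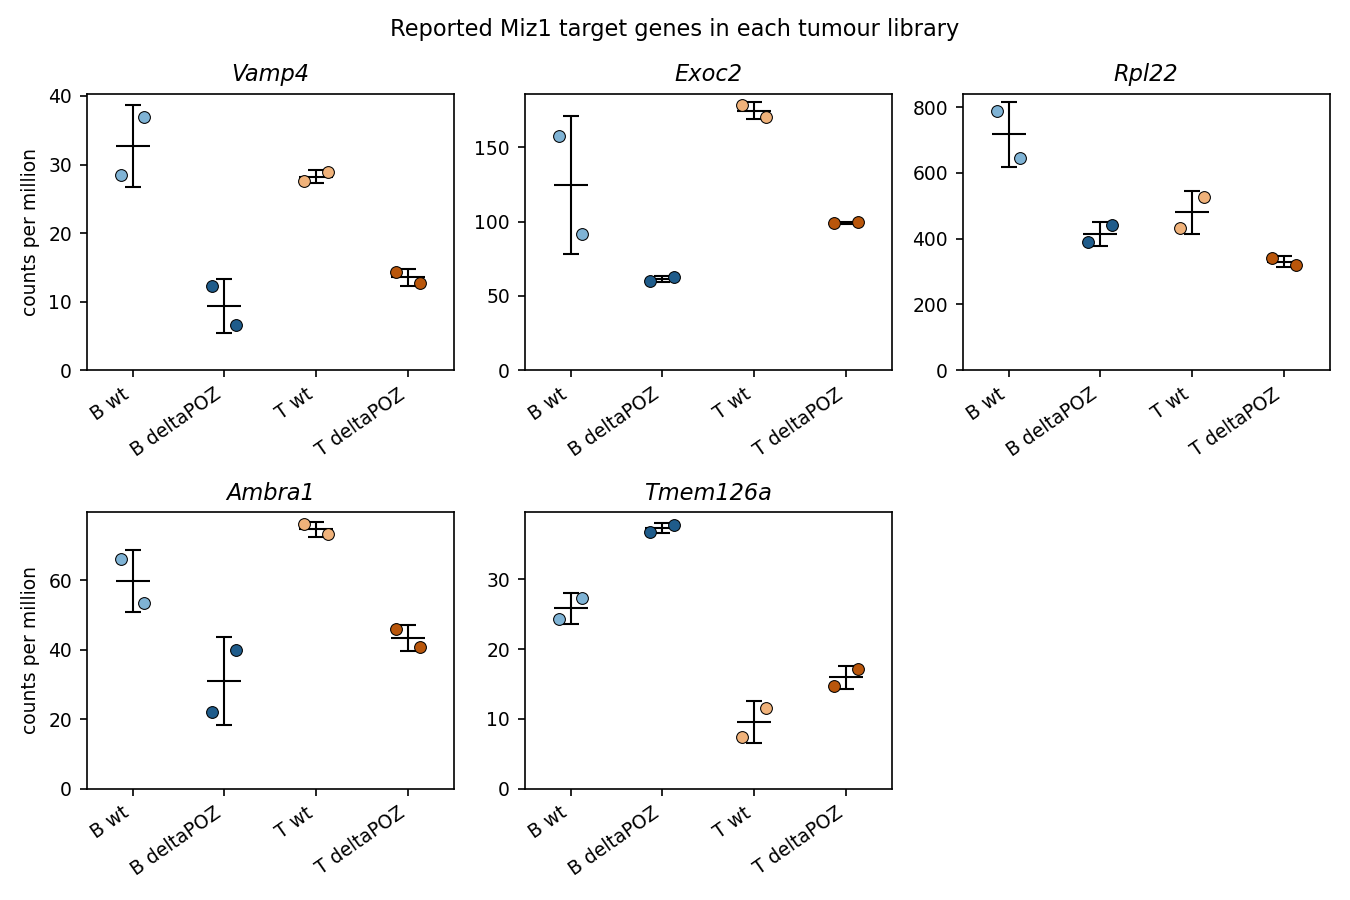
CPM (vertical axes) of 5 reported Miz1 target genes in the 4 groups, with a point for each library and a bar for the mean with its SD (n = 2). Vamp4 is at 28.4 and 36.9 in B wt against 12.2 and 6.62 in B deltaPOZ, and at 27.6 and 28.9 in T wt against 14.4 and 12.7 in T deltaPOZ.

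In the B tumours deltaPOZ was compared with wt to see what the deletion changes in B cell leukemia. Platr10, a long noncoding RNA gene (ENSMUSG00000099370, chromosome 3, 75647446 to 75655731), rose from 0.406 ± 0.070 to 63.2 ± 9.4 CPM, a log2 fold change of 7.27 (SE 0.39, edgeR adjusted p = 0.0335). It was the only gene of 16456 past the threshold by edgeR, with 1996 at an unadjusted p under 0.05; limma-voom called 6 and DESeq2 682 (295 higher, 387 lower). Its call was lost without B wt 1, B wt 2, B deltaPOZ 1, T deltaPOZ 1 or T deltaPOZ 2, each of which left a count of 0, while the fit without B deltaPOZ 2 called 9 genes and those without either T wt library 6 each. With the 3 doubted libraries left out, 1 gene was called, lower. Platr10 lies on chromosome 3, which was raised in B deltaPOZ 1, yet stood at 69.8 and 56.6 CPM in both B deltaPOZ libraries.

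At an adjusted p under 0.1, 39 genes were listed in B, 12 higher and 27 lower. Erg, a transcription factor of early blood and B progenitor cells, stood at 16.3 ± 6.8 CPM in wt and 0.108 ± 0.068 in deltaPOZ (log2 fold change -7.20, SE 0.99, adjusted p = 0.0819). Adgrg1, an adhesion receptor gene, stood at 18.1 ± 8.7 against 0.198 ± 0.17 (-6.50, SE 0.66, 0.0638), and Asb2, a ubiquitin ligase subunit gene on chromosome 12, at 39.8 ± 4.7 against 2.54 ± 0.77 (-3.97, SE 0.39, 0.0638). Others with lower levels were Tmem119 (-8.92), Cntln (-6.71), the zinc finger factor gene Insm1 (-6.29), Sccpdh (-4.48), the kinesin gene Kif13a (-4.38), Lrfn4 (-4.26) and Mvb12b (-4.01). Higher levels were seen for Cpn1 (8.78), the glycine transporter gene Slc6a9 (5.11), Asph (3.84), Hus1b (3.70), the Wnt receptor gene Fzd9 (3.62) and Atxn1 (2.89). The Y-linked Eif2s3y (10.48), Uty (10.18) and Ddx3y (9.66) were also on the list, as the sexes of the mice require. None of these passed 0.05 by edgeR.

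Genes of precursor B cells were lower in B deltaPOZ tumours. All 14 measured members had negative fold changes with a median of -1.96. Erg, Vpreb1 (20.6 ± 1.9 against 0.498 ± 0.62 CPM, log2 fold change -5.37, SE 1.15), which encodes part of the surrogate light chain, and Arpp21 (-4.73, SE 1.20) fell when adjusted over the list alone, with edgeR adjusted p from 0.00258 to 0.0270, and 0 members passed over all genes. Erg passed over the list alone without each of the 8 libraries in turn. Vpreb1 failed without B wt 2, and Arpp21 without B wt 2, B deltaPOZ 1 or B deltaPOZ 2. The camera adjusted p of the list was 7.91e-07, and the adjusted p was 0.426 with an estimated correlation. The B lineage identity genes such as Pax5 had a smaller median of -0.57, with 14 of 16 lower, and did not pass (camera adjusted p = 0.109). They were called lower in 3 of the 8 fits without 1 library, and with the 3 doubted libraries named above left out. Sex and the distal part of chromosome 4 moved with the same groups. B deltaPOZ 2 stood apart on some members, with Rag1 at 50.3 CPM against 920 in B deltaPOZ 1, Rag2 at 5.34 against 46.8, and Dntt at 0.0399 against 0.449.

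**Figure D3:**
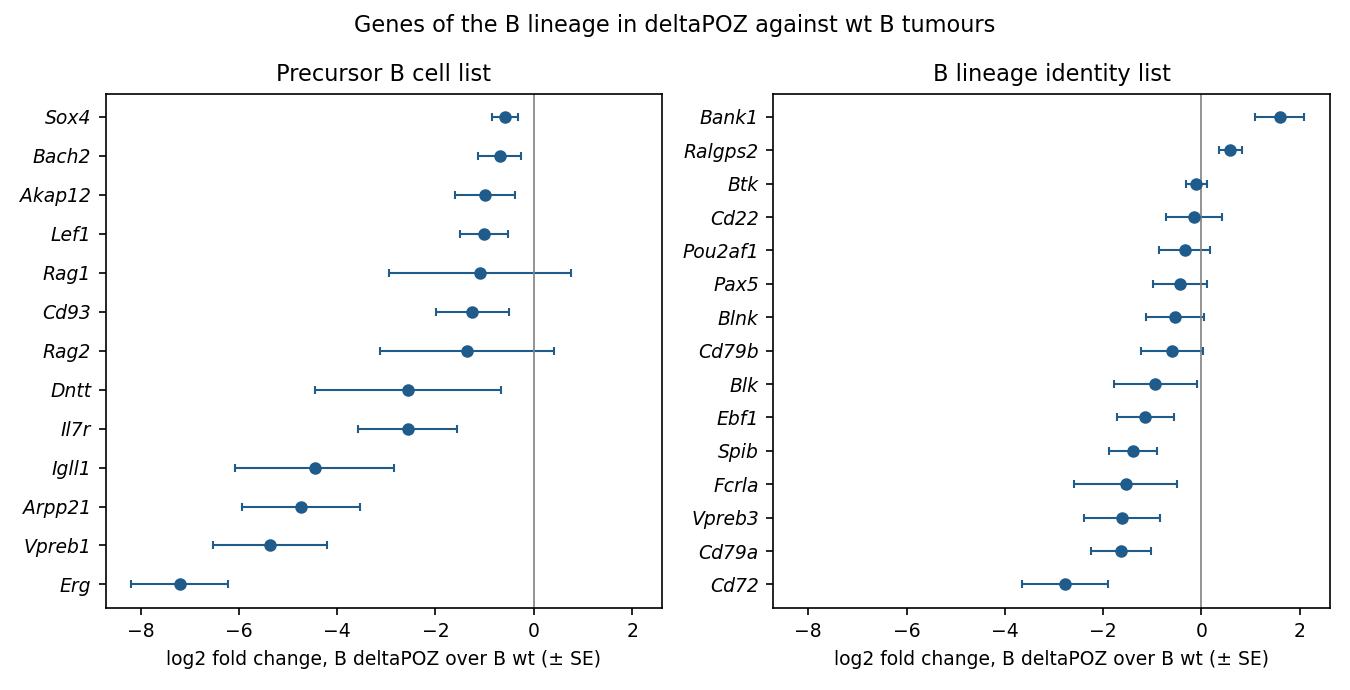
Log2 fold change of B deltaPOZ over B wt (horizontal axes) with its SE for 13 precursor B cell genes and 15 B lineage identity genes (vertical axes), from 2 libraries per group. The 13 precursor genes shown lie below 0, down to -7.20 for Erg, and the fourteenth member, Vpreb2, is not drawn because it had no counts in B deltaPOZ.

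Genes of growth induced by Myc and of glycolysis were higher in B deltaPOZ tumours. All 30 genes of the list of ribosome biogenesis and growth genes induced by Myc had positive fold changes, with a median of 0.51. They included Polr1b, a subunit of RNA polymerase I (217 ± 42 against 421 ± 69 CPM, log2 fold change 0.96, SE 0.28), and Srm, which makes spermidine (77.4 ± 35 against 200 ± 14, 1.37, SE 0.40). The camera adjusted p was 7.91e-07, and the adjusted p was 0.709 with an estimated correlation. Of 22 genes of glycolysis and hypoxia 17 were higher (camera adjusted p = 0.00295; adjusted p = 0.426 with an estimated correlation). The glycolytic enzyme gene Eno1 rose from 448 ± 60 to 994 ± 73 CPM when adjusted over the list alone (log2 fold change 1.15, SE 0.18, edgeR adjusted p = 0.0080); this call was lost without B wt 1 (0.0805), with the B libraries fitted alone (0.0538), with the 3 doubted libraries left out (0.0763) and, since Eno1 lies there, without chromosome 4. Members that passed over all genes numbered 0 in both lists. Eno1 and Srm lie in the distal part of chromosome 4, where their neighbours within 10 Mb had a median fold change of 0.68. With all genes of chromosome 4 left out, the growth list kept an adjusted p of 7.97e-07 and the glycolysis list one of 0.00339.

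Other groups also passed camera in B. The 26 histone genes were all lower (median -0.52, adjusted p = 6.22e-05), and 24 of 30 genes of the G2 and M phases were lower (median -0.29, 0.00214), among them Cdk1, the kinase that starts mitosis (305 ± 37 against 201 ± 7.3 CPM). Of 16 NF-kB response genes 13 were lower (0.0125), and the inhibitors Tnfaip3 (14.5 ± 0.34 against 7.79 ± 0.065), Nfkbie and Nfkbia fell when adjusted over the list alone (edgeR adjusted p = 0.0366 each). No fit without 1 library kept all 3 of these: 2 passed without B wt 2, 1 other gene without B wt 1, and 0 without any of the other 6 or with the B libraries fitted alone; limma-voom and the fit without the 3 doubted libraries also gave 0. Genes of antigen presentation on MHC class II were higher in 8 of 10 cases (0.00492), as with Cd74, the invariant chain (174 ± 120 against 564 ± 78), and interferon response genes in 27 of 31 cases (0.0018). With an estimated correlation the adjusted p of these 5 lists was 0.426 to 0.712. The call of G2 and M genes was lost without B deltaPOZ 2 (0.0808), that of NF-kB genes without B deltaPOZ 2 (0.0682) and that of MHC class II without B wt 1 (0.0523) or B deltaPOZ 1 (0.115). The interferon genes turned direction without B deltaPOZ 1 (0.924).

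Markers of other cells moved with genotype in B as well. All 15 erythroid genes were higher in deltaPOZ (camera adjusted p = 2.91e-06; adjusted p = 0.709 with an estimated correlation; median 3.96, or 3.79 with a gene at 0 set to its bound). Most of this came from B deltaPOZ 2, yet without that library the adjusted p was 0.0050. All 15 neutrophil genes were lower (median -2.94, 6.22e-05; adjusted p = 0.709 with an estimated correlation), with an adjusted p of 0.0442 without B wt 2. The sex-linked list passed (6.22e-05; 0.426 with an estimated correlation). Lists of regulatory and effector T cells (higher, 0.0217), the BCL2 family (lower, 0.0315), cholesterol synthesis (lower, 0.0328) and oxidative phosphorylation (higher, 0.0404) passed too, with adjusted p from 0.426 to 0.723 with an estimated correlation. Their calls were lost without B wt 1 (0.273, 0.0523, 0.283 and 0.0523 in that order). The calls of the last 3 were also lost without B deltaPOZ 2 (0.113, 0.395 and 0.267), and that of T cell genes without B deltaPOZ 1 (0.376). Without the genes of chromosome 4 the calls of T cell genes (0.0834), cholesterol synthesis (0.0577) and oxidative phosphorylation (0.0618) ended. The BCL2 family lost its call without B wt 2 (0.111) or T deltaPOZ 1 (0.0834), and oxidative phosphorylation without any library but B deltaPOZ 1 (0.0504 to 0.267). The other 25 of the 40 lists had adjusted p from 0.0586 to 0.973 in B.

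In the T tumours the same comparison asked what the deletion changes in T cell leukemia. The deposited names of the T deltaPOZ libraries carry the tag ENU and those of T wt do not, so the T tumours of each genotype may have arisen in unlike ways. The labels do not say, and every value that rests on T, with the average and the difference, stands under this doubt. By edgeR 0 genes passed, with 436 at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 51 (20 higher, 31 lower). The smallest p among protein coding genes belonged to Lsp1, a leukocyte actin-binding protein gene, at 75.4 ± 2.5 CPM in wt and 20.6 ± 2.2 in deltaPOZ (log2 fold change -1.87, SE 0.21, edgeR adjusted p = 0.417), and Rmnd5a, part of a ubiquitin ligase, at 1141 ± 285 against 291 ± 36.4 (-1.97, SE 0.27, 0.855). The receptor segments Trbv26 (-6.91) and Trbv13-3 (-9.98) and the gene Gm9522 (-4.38) completed the 5 smallest. Trbv13-3 stood at 50.0 and 481 CPM in the T wt libraries.

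By camera 19 of 40 lists passed in T, among them those of S phase, G2 and M phase, cholesterol synthesis and platelets. Of 29 S phase genes 28 were higher (median 0.28, camera adjusted p = 4.72e-06), including Cdca7 (312 ± 6.5 against 433 ± 21 CPM), Uhrf1, which maintains DNA methylation (336 ± 37 against 458 ± 22), and Gins2, part of the replicative helicase (19.3 ± 0.033 against 26.7 ± 0.76). Of 30 genes of the G2 and M phases 28 were lower (median -0.20, 0.000909). Of 18 genes of cholesterol synthesis 17 were lower (median -0.36, 0.000909), with Srebf2, which switches on the pathway, at 207 ± 33 against 120 ± 36. All 10 megakaryocyte and platelet genes were higher (median 1.38, 1.69e-08), at low levels, with Pf4 at 0.856 ± 0.37 against 3.33 ± 1.2. With an estimated correlation the adjusted p of these 4 lists was 0.648 to 0.681. In T 0 members of any list passed over the list alone or over all genes by edgeR in the fit of all libraries. Reported Miz1 targets did in some other fits, 4 with the filter of 5 CPM and 3 with T alone, and 4 precursor B cell genes did without T deltaPOZ 2. The call of S phase was lost without T wt 1 (0.0785), and that of cholesterol synthesis without T wt 2 (0.157) or T deltaPOZ 2 (0.121). With the 3 doubted libraries left out, S phase and platelet genes had an adjusted p of 0.0858, G2 and M genes 0.0447 and cholesterol genes 0.0356.

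Another 14 lists passed camera in T, besides the reported Miz1 targets. Higher in deltaPOZ were the growth genes induced by Myc (28 of 30, adjusted p = 0.00322), MHC class II (9 of 10, 0.00367), mature B cell (0.00731), B lineage identity (0.00824), ribosomal protein (70 of 79, 0.00824), oxidative phosphorylation (0.0136), glycolysis (0.0162), macrophage (0.0292), stroma (0.0362) and DNA damage (0.0416) genes. Lower were interferon response (28 of 31, 0.00646), autophagy (0.00975), regulatory and effector T cell (0.0218) and plasma cell (0.0362) genes. With an estimated correlation their adjusted p was 0.648 to 0.819. None of the 14 kept its call without each library in turn. Without T wt 1, which held the most Xist, the adjusted p reached 0.952 for growth genes, 0.952 for ribosomal proteins, 0.851 for oxidative phosphorylation, 0.126 for glycolysis, 0.454 for macrophage genes, 0.713 for stroma, 0.966 for DNA damage, 0.503 for interferon genes, 0.680 for T cell genes and 0.363 for plasma cell genes. Without T wt 2 it reached 0.624 for MHC class II, 0.632 for mature B cells, 0.377 for autophagy and 0.0820 for glycolysis, and B lineage genes turned direction (0.923). Without T deltaPOZ 1 growth genes turned direction (0.726), and 8 other calls were lost: B lineage (0.1002), ribosomal proteins (0.0680), oxidative phosphorylation (0.205), glycolysis (0.186), macrophage (0.186), DNA damage (0.700), autophagy (0.0640) and plasma cell genes (0.0806). Without T deltaPOZ 2 stroma genes turned direction (0.933), and the other lists but growth and DNA damage had adjusted p from 0.0602 to 0.133. Stroma, plasma cell and DNA damage calls also ended at 0.0509 to 0.0714 without single B libraries, and that of DNA damage without chromosome 4 (0.0504). The other 21 lists had adjusted p from 0.0511 to 0.936 in T; the neutrophil list had a negative median (-0.84) and the opposite sign in its test.

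**Figure D4:**
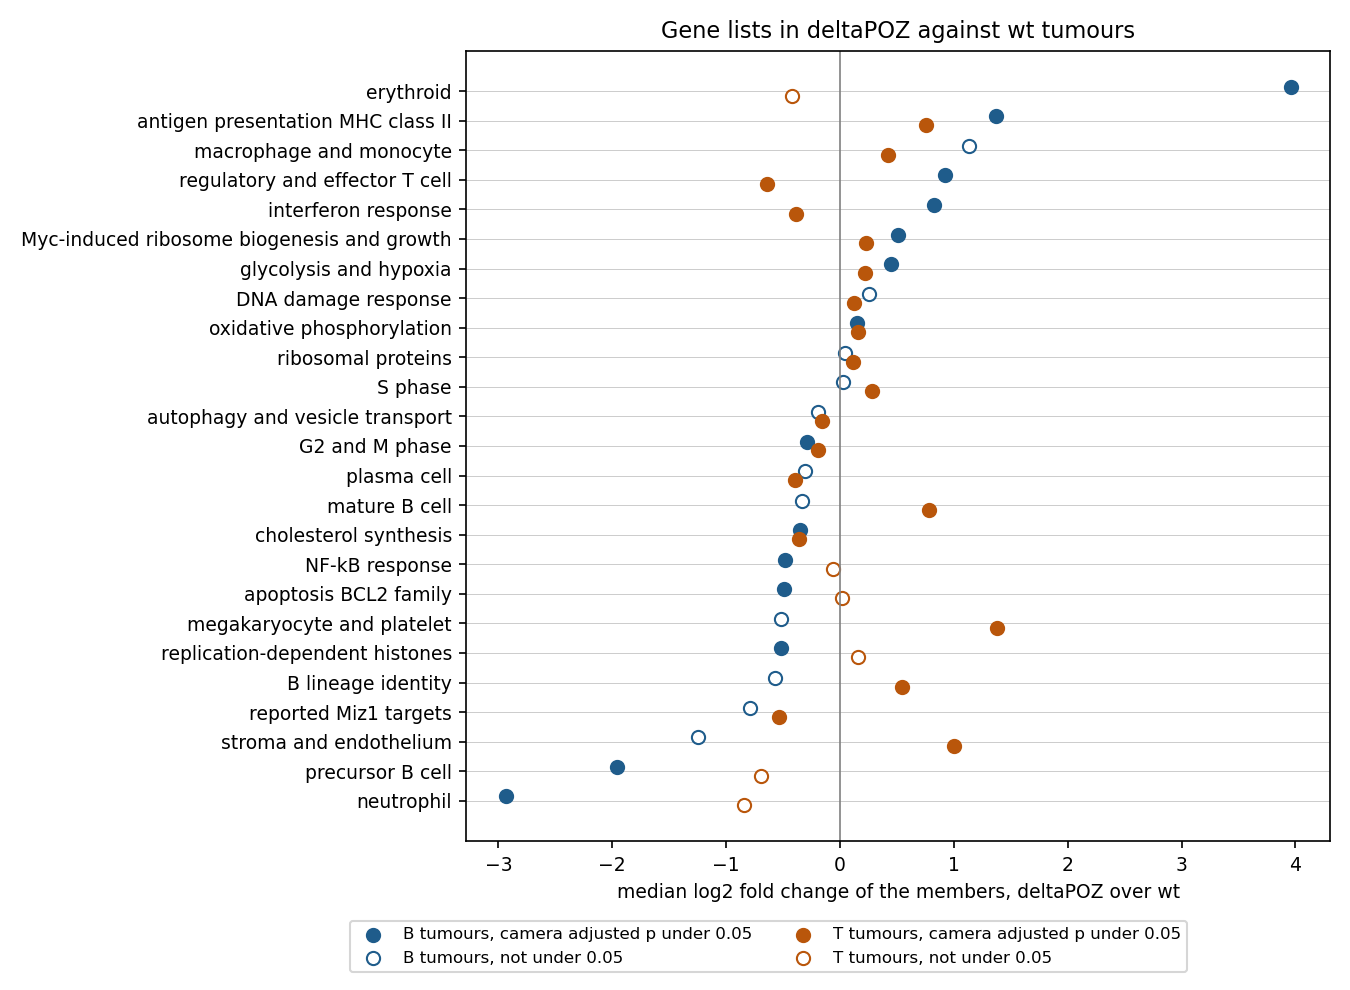
Median log2 fold change of deltaPOZ over wt (horizontal axis) of the gene lists (vertical axis) that passed camera in B or T, without the sex-linked list, with filled points for an adjusted p under 0.05 at the preset correlation. Precursor B cell genes have a median of -1.96 in B, S phase genes 0.28 in T, and reported Miz1 targets -0.79 in B and -0.54 in T.

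The mean of both effects asked what the deletion changes in either lineage. By edgeR 0 genes passed, with 1464 at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 318 (123 higher, 195 lower). Fits without T wt 1 and T wt 2 called 2 and 5 genes. Ifi209, an interferon-inducible gene of the p200 family (ENSMUSG00000043263, chromosome 1, 173630917 to 173647928), had the smallest p, at 306 ± 6.1 against 80.8 ± 1.6 CPM in B and 27.4 ± 2.4 against 14.4 ± 0.77 in T (mean log2 fold change -1.42, SE 0.11, adjusted p = 0.0804). Snx18, a membrane remodelling gene, stood at 37.8 ± 0.25 against 3.88 ± 2.2 in B and 41.1 ± 6.1 against 11.8 ± 0.64 in T (-2.54, SE 0.29, 0.203). Adgrg1 (-3.57), Tmx4 (-1.38) and Platr10 (5.43) followed with the same adjusted p. Platr10 stood at 0 to 0.033 CPM in the T libraries, within the limit for a count of 0, so its mean rests on B.

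Growth genes induced by Myc were higher for all 30 members (median 0.36, camera adjusted p = 7.85e-08), with the nucleolar chaperone gene Npm1 at 1191 ± 132 against 1686 ± 243 CPM in T. Precursor B cell genes were lower for all 14 (-1.11, 3.09e-07), genes of the G2 and M phases for 26 of 30 (-0.23, 5.39e-05) and cholesterol synthesis genes for 16 of 18 (-0.39, 0.000575). In T the precursor list did not pass (9 lower and 4 higher, camera adjusted p = 0.0511). Erg and Vpreb1 stood at no more than 0.878 CPM there. The effect on this list differed between the lineages (camera adjusted p = 0.00101, or 0.752 with an estimated correlation), so its average rests mostly on B. MHC class II genes were higher for all 10 (1.10, 0.000179). So were 18 of 22 genes of glycolysis (0.35, 0.000575), of which Eno1, Pgam1, Tpi1, Ldha and Pkm rose when adjusted over the list alone (edgeR adjusted p from 0.0240 to 0.0450) and 0 over all genes. Without B wt 1, B deltaPOZ 2, T wt 2 or T deltaPOZ 1 none of these 5 passed over the list alone, and without the other libraries 2 to 3 did. With the 3 doubted libraries left out 0 did (smallest edgeR adjusted p = 0.112). These 6 lists kept their call without each library in turn, and the adjusted p was 0.284 to 0.625 with an estimated correlation. The sex-linked list (0.000124; 0.284 with an estimated correlation) and the platelet list (0.00322; 0.558) did so too.

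The other lists that passed in the average, besides the reported Miz1 targets, each lost the call without at least 1 library. They were erythroid (higher, 0.000636), neutrophil (lower, 0.00246), oxidative phosphorylation (higher, 0.00281), NF-kB (lower, 0.00687), autophagy (lower, 0.00949), DNA damage (higher, 0.0157), macrophage (higher, 0.0161) and thymocyte stage genes (lower, 0.0303). S phase and ribosomal protein genes (higher) and plasma cell and histone genes (lower) had 0.0388 each. With an estimated correlation their adjusted p was 0.410 to 0.833. Without T wt 1 the calls of erythroid (0.133), neutrophil (0.210), oxidative phosphorylation (0.103), NF-kB (0.133), DNA damage (0.231), macrophage (0.101), thymocyte (0.101), S phase (0.435), ribosomal protein (0.560) and plasma cell genes (0.133) ended. Autophagy genes lost theirs without B wt 1 (0.231) or T wt 2 (0.102), and histones without T wt 2, where they turned direction (0.682). Leaving out B wt 1, B wt 2, B deltaPOZ 1, B deltaPOZ 2, T deltaPOZ 1 or T deltaPOZ 2 ended 3 to 7 of these calls each, with adjusted p of at most 0.310, 0.755, 0.784, 0.412, 0.545 and 0.152 in that order. Erythroid and oxidative phosphorylation genes lost theirs only without T wt 1. In T all 15 erythroid genes were lower (median -0.42) and 22 of 26 histone genes higher (median 0.16), and neither list passed camera there. Their averages thus carry the sign of B, not of T. With the 3 doubted libraries left out, neutrophil genes turned direction (0.00297), and erythroid genes had 0.900. Without chromosome 4 S phase genes had 0.0525 and histones 0.0511. Over the list alone 3 autophagy genes fell, which were the Miz1 targets Vamp4, Exoc2 and Ambra1. The other 19 lists had adjusted p from 0.0965 to 0.946.

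The difference of the effects (T minus B) asked whether the lineages respond unlike each other. By edgeR 0 genes passed, with 1030 at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 225 (154 higher, 71 lower), and the fit without T wt 1 called 4. The smallest p belonged to Igfbp4, which binds insulin-like growth factors, at 104 ± 24 against 11.1 ± 1.7 CPM in B and 1.31 ± 0.35 against 2.26 ± 0.11 in T (4.01, SE 0.41, edgeR adjusted p = 0.259). Spsb4 (8.60), Asb2 (4.34), the tetraspanin gene Cd37 (1.98) and Hus1b (-5.09) had the same adjusted p. Gins2 of the S phase list (B 44.0 ± 0.67 against 22.6 ± 2.5) differed when adjusted over the list alone (1.43, SE 0.28, edgeR adjusted p = 0.0407), as did Erg (7.56, SE 1.21, 0.0064). As sets, 12 of 40 lists differed by camera and 28 did not (adjusted p from 0.0539 to 0.996); with an estimated correlation 0 did (0.752 to 0.955 for those 12).

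Across the 16456 genes the fold changes in B and T had a Pearson correlation of -0.05 and a Spearman correlation of 0.06, with equal signs for 54.9% of genes; genes are not independent replicates. Without single libraries Pearson's value ran from -0.11 to 0.11 and Spearman's from -0.03 to 0.18. With the filter of 5 CPM Spearman's value was 0.18, with equal signs for 58.8% of genes. Genes at an unadjusted p under 0.05 in both lineages in the same direction numbered 23 higher and 37 lower, against 12.2 and 14.3 for independent lists. Both lists came from the same fit with a shared estimate of each gene's spread, so they were not independent. The excess alone therefore does not show shared effects.

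The contrast of T with B tumours describes the lineages named by the labels. The deposited names carry 1 run tag for all B libraries and another for all T libraries, so lineage and run cannot be told apart. Cd3e, a T cell receptor subunit gene, stood at 90.7 ± 3.8 and 82.2 ± 5.3 CPM in T wt and T deltaPOZ against 0.239 ± 0.070 and 0.236 ± 0.14 in B wt and B deltaPOZ (log2 fold change of T over B 8.50, SE 0.32, edgeR adjusted p = 9.66e-05). All 20 T lineage genes were higher in T, among them Sh2d1a (8.14), Tcf7 (7.88) and Trat1 (7.74), and all 20 passed over all genes and over the list alone. All 16 B lineage genes were lower in T, among them Vpreb3 (-8.05), Ebf1 (-5.32) and Cd79b (-5.03), with 15 called over all genes and 16 adjusted over the list alone. Cd8a stood at 356 to 1246 CPM and Cd4 at 98.8 to 432 in the T libraries. All 79 ribosomal protein genes had lower levels in T (67 called over all genes, 73 over the list alone), and all 15 erythroid genes higher ones, all called both ways. By edgeR 5801 genes were called, 3176 higher and 2625 lower in T, and 1312 with the 3 doubted libraries left out. Without T deltaPOZ 2 and T wt 1 the fits called 3621 and 3840.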

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

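Beyond the average effect, 12 lists had unlike deltaPOZ effects in T and B by camera on the difference of the fold changes, tested as planned before the data were examined. With an estimated correlation their adjusted p was 0.752 to 0.955. Interferon response genes had a lower effect in T for 28 of 31 members (median -1.15, adjusted p = 8.5e-06; 0.0935 without B deltaPOZ 1). Histone genes had a higher effect for all 26 (0.69, 8.5e-06; 0.0614 without T wt 1). Erythroid genes (lower in T, 8.5e-06), platelet genes (higher, 0.000114) and sex-linked genes (lower, 9.43e-05) differed in every fit without 1 library. Neutrophil genes differed (higher, 0.00079), but not without B wt 2 (0.0891), T wt 2 (0.440) or T deltaPOZ 1 (0.0629). Regulatory and effector T cell genes (lower, 0.00093) did not without B deltaPOZ 1 (0.0513). Precursor B cell genes had a higher effect for 12 of 14 members (median 1.81, 0.00101; 0.186 without T deltaPOZ 2). S phase genes differed (higher, 0.00263), but not without B deltaPOZ 2 (0.0582), T wt 1 (0.174) or T deltaPOZ 1 (0.0629). B lineage identity genes differed (higher, 0.00367), but not without B wt 1 (0.158) or T wt 2 (0.120). Growth genes induced by Myc (lower, 0.0191) did not without B wt 1 (0.438), B deltaPOZ 2 (0.114), T wt 2 (0.585) or T deltaPOZ 2 (0.815). Mature B cell genes (higher, 0.0244) did not without B wt 1 (0.1295), B deltaPOZ 2 (0.0766), T wt 2 (0.333), T deltaPOZ 1 (0.0559) or T deltaPOZ 2 (0.105).

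T deltaPOZ 2 had 2.13 alignments at more than 1 place per gene count, against 1.36 to 1.58 in the others, and 3267 genes with counts in it alone against 111 to 374.

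Of the count tests below, the 2 on splits of the libraries were set before the results were seen, and all other tests of explanations afterwards. For the average effect 0 genes were called, and the highest count of another split was 1. With a count of 0 all 18 splits must give as many, so this test decides nothing. For T against B, a fit with 2 groups called 5405 genes and 1 of 35 splits did as well, the real one.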

How the results depend on the processing

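Genes called in B numbered 9 with the filter of 5 CPM, 6 by limma-voom, 682 by DESeq2, 6 with the lineage alone and 39 at a threshold of 0.1, and 0 to 9 without single libraries. In T DESeq2 called 51. In the average DESeq2 called 318, the additive model 1, the threshold of 0.1 gave 1, and fits without single libraries 0 to 5. For the difference DESeq2 called 225 and fits without single libraries 0 to 4. T against B had 1312 with 3 doubted libraries left out and 3621 to 4900 without single ones. With an estimated correlation 0 lists were called in B, T, the average and the difference. Fry called 2, 0, 2 and 0 in that order. In B and in the average these were the reported Miz1 targets (lower) and the sex-linked genes (higher). With the 3 doubted libraries left out, the B calls of interferon, BCL2 family and oxidative phosphorylation genes ended. B lineage identity, autophagy, NK and stroma genes gained a call in B in that fit. With 3 libraries left out 11 lists were called in T, 11 in the average and 7 in the difference; without single libraries 7 to 20 in T and 12 to 21 in the average.

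With 3 left out, directions of called lists turned for ribosomal proteins in T (camera adjusted p = 0.824) and the average (0.297), stroma in T (0.0183) and neutrophils in the average (0.00297). Lists not called before passed in the other direction, on 1 residual degree of freedom with 1 library against 1 in T: histones in T (lower, 9.74e-06) and stroma in B (higher, 0.0189) and the difference (lower, 0.00423). Without single libraries camera adjusted p ran from 3.52e-10 to 0.924 for interferon genes in B, 2.59e-11 to 0.923 for B lineage identity in T, 2.69e-07 to 0.952 for growth genes in T, 0.00123 to 0.933 for stroma in T, 4.48e-07 to 0.682 for histones in the average and 0.447 to 0.884 for Miz1 targets in the difference. Zbtb17 in B ran from -0.23 to 0.18. The Pearson correlation of B and T fold changes was 0.0466 with the strict filter and -0.113 to 0.106 without single libraries. A group that lost a library kept 1, assumed to vary like the others; the cause of these shifts was not tested. Of named genes Platr10 in B lost its call without 5 single libraries and without the 3 and Zbtb17 in B turned sign in 2; most others were never called, so that they stayed so says little.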

Other observations

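Hes5, a target of Notch signalling picked after its values were seen, stood at 6.85 and 5.19 CPM in T wt against 18.6 and 22.3 in T deltaPOZ. In B it went the other way at low levels, from 2.05 and 2.29 CPM in wt to 0.312 and 0.678 in deltaPOZ. Its effects in T and B differed when adjusted over the list of Notch genes alone (3.89, SE 0.64, edgeR adjusted p = 0.00943), not over all genes. The deposited names of all T libraries, and of no B library, carry the tag Notch, which the labels do not explain, so a difference in Notch genes between T and B stands under that doubt. Notch1 stood at 767 and 946 CPM in T wt and at 286 and 891 in T deltaPOZ. Cdkn2a, a tumour suppressor gene, stood at 90.7 CPM in B deltaPOZ 2.

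Receptor segments differed between the tumours. Trbv16 stood at 155 and 451 CPM in T wt 1 and T deltaPOZ 1 against 0.829 and 1.44 in the other T libraries. Trbv20 stood at 135 in T wt 1, 54.6 in T wt 2, 0.293 in T deltaPOZ 1 and 378 in T deltaPOZ 2, Ighv7-3 at 105 in B wt 1 and Iglv1 at 196 in B deltaPOZ 1.

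The tests of explanations in this and the next 2 paragraphs were chosen after the results were seen. For the lower reported Miz1 targets, the dosage of their chromosome regions was weighed by setting the 5 members that fell against their neighbours within 10 Mb. The median difference stayed at -0.99 (SD 0.197), with neighbour medians from -0.14 to 0.34 in the average. Regional dosage therefore does not account for the fall of these 5. They were chosen because they fell, so this says nothing of the other members of the list. Sex could still contribute in both lineages. In B it followed the genotype in every library, so there it cannot be told apart from the deletion. In T, without T wt 1, which held the most Xist, the median of the 5 was -0.784 (SD 0.288), yet only 1 T wt library remained. Tumours from wt and deltaPOZ mice of the same sex would settle it.

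For the lower precursor B cell genes, fewer B lineage cells in B deltaPOZ would need a like fall of B lineage identity genes, whose median was -0.569 (SD 1.02) against -1.96. Of the 16 identity genes 14 were lower, so fewer such cells could still make a part of the fall. Other cells in B wt 2 are not needed for the fall, since the median without that library was -1.66. Only 1 B wt library remained then, so this cannot separate the genotype from that single tumour. Sex followed the genotype in 4 of 4 B libraries, so it cannot be told apart from the deletion there. Genes of mature B cells were not higher (9 of 13 lower, median -0.33, camera adjusted p = 0.321), nor those of plasma cells (7 of 10 lower, median -0.31, 0.221). More B tumours per genotype, all of 1 sex, would separate sex from the deletion.

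For the whole-chromosome shifts, normalization would move the other autosomes too, yet the genes of all other autosomes pooled had a median of at most 0.0554 in the shifted libraries, though single ones reached -0.26. The normalization itself draws such a pooled median towards 0, so this value decides little. At least 86.2% of the expressed genes of each shifted chromosome lay above the other libraries. These chromosomes were picked by a median over 306 to 545 genes, which a few strong genes cannot move. That choice settled the test in advance. Extra copies in the tumour cells could give such shifts, with 0.373 as the lowest median of either part of a shifted chromosome split at its middle gene against 0.585 for 3 copies over 2. DNA was not measured, so this is a hypothesis that DNA sequencing of the same tumours would test.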
